A study of Rattus norvegicus with 8 samples.

How the data were processed

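Messenger RNA of the orbitofrontal cortex was sequenced from 8 adult male Sprague-Dawley rats, an outbred strain. Per the labels' protocols, 4 animals had received a scrambled siRNA and 4 an siRNA against the backsplice junction of circNrxn3, a circular RNA made from the neurexin 3 gene, 7 days before the tissue was taken. The libraries were made from poly-T selected RNA with a strand-marking (dUTP) method, per the labels' protocols. Circular RNAs have no poly-A tail, so gene counts from such libraries hold mainly linear mRNA.

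The deposited count table gives whole-number read counts per gene, 1 column per sample, with no normalization. The submitters' processing notes name fastp, HISAT2 2.0.5, StringTie 1.3.3b, featureCounts 1.5.0-p3 and the genome build rn6, without their roles, order or settings. Whether strand was used in counting is not given in the sources used here, so reads of overlapping genes on opposite strands may not be told apart. The authors also deposited FPKM values for the same genes, that is, read counts scaled by the length of the gene model and by a library total. Dividing the counts by these FPKM values and the gene length gave 1 total per sample, and these totals were proportional to median-of-ratios size factors, so the FPKM values were already scaled between samples. The table holds 34298 genes, of which 11107 had 0 counts in all 8 samples.

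Samples were assigned to groups from their titles and treatment labels, and both count and FPKM columns were matched to samples by title. Total counts per library ran from 27589883 to 35221782. As a check for a library deposited more than once, the counts of each pair within a group were compared, and no pair agreed within sampling noise (chi-square per degree of freedom of 23.2 to 47.4 over genes with at least 20 counts in a pair). Each library was taken as 1 replicate because the labels call the samples of a group biological replicates, and p-values measure the spread between these animals.

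The comparison of the siRNA groups was fitted with edgeR 4.0.16 in R 4.3.3 on the counts as deposited. Genes were kept by filterByExpr with its default minimum count of 10 (16573 genes), libraries were scaled with TMM factors, and the quasi-likelihood F test with robust dispersions was run without covariates. P-values were 2-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Fold changes are log2 values of circNrxn3 siRNA over scrambled siRNA, the standard error is the fold change divided by the square root of F, and levels are CPM, counts scaled to a common library total with the TMM factors.

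Before the data were examined, the test, its alternatives, a rule for the genes named and 42 gene lists covering synaptic, cell type, organelle, stress and immune genes were fixed. The rule names Nrxn3 and Nrxn2 always, and 1 further gene that is not reported here. With fewer than 10 genes past the threshold in a direction, it adds the genes with a symbol and the smallest unadjusted p until 10 are named in that direction, given as values that did not pass, and for each list described it names 2 to 4 members with the smallest p. A gene named outside this rule is said to have been chosen after its values were seen. Of 826 distinct symbols in the 39 lists written by name, 786 were found among the protein-coding genes of the table, 8 more through the synonyms in a RefSeq table of the GRCr8 assembly, and 32 were not found; 3 lists were defined by symbol patterns. Lists were tested with camera (limma 3.58.1) at its preset correlation of 0.01, with adjustment over the 42 lists, and again with an estimated correlation and with fry. A list score is the mean, over the list's members in a library, of log2 CPM (prior count 2) minus each member's mean over the 8 libraries. Scores and library measures were compared between the groups with 2-sided exact permutation tests over the 70 arrangements of the labels, whose smallest possible p is 0.0286.

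The procedure was tested on simulated data. Counts for the 16573 genes were drawn with the real means, dispersions and library sizes in 5 data sets, each with 200 changed genes. The changed genes were taken from those with a mean CPM of at least 1, so recovery at lower levels was not measured. In this comparison of 4 against 4, 2.4% of genes changed 1.25-fold were recovered, 25.2% of those changed 1.5-fold, 60.8% of those changed 2-fold and 84.4% of those changed 4-fold. Of 462 calls 30 were false, and in a further data set with no change simulated 0 genes and 0 lists were called. The simulated genes vary independently, unlike genes that share a pathway or a cell type, so the simulation does not test the camera p-values of correlated lists.

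Alternatives were other scalings (RLE, upper quartile), other filters (none, a CPM of at least 1 in 4 samples), DESeq2 1.42.0, limma-voom, non-robust dispersions, limma with a mean-variance trend on log2(FPKM + 1) and log2(FPKM + 0.1) with several filters, protein-coding genes alone, the replicate number as a block, each library left out in turn, counts thinned to the smallest library, 1 surrogate variable from sva 3.50.0, and a threshold of 0.10. After seeing the data, 2 more were added, the removal of each library's trend with gene length and a fit without the 3 libraries lowest in long transcripts. All 35 splits of the 8 samples into 4 and 4 were enumerated as a further check. Predicted siRNA seed matches in 3′ untranslated regions were not analysed, since no transcript sequences were used.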

Results

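The orbitofrontal cortex of adult male rats was profiled by RNA sequencing 7 days after local infusion of an siRNA with the JetPEI transfection reagent. The infusion held 5 ng of siRNA in 1 µl. In 4 animals the siRNA was a scrambled control (replicates 1, 3, 4 and 5), and in 4 it was directed at the backsplice junction of circNrxn3, a circular RNA spliced from neurexin 3 transcripts (replicates 1 to 4). The sense strand of this siRNA was UCCAAAGGCUAGACAGGAAUU and the antisense strand UUCCUGUCUAGCCUUUGGAUU. Libraries of the second group are called knockdown libraries after their labels. Total counts were 31899900 ± 3615600 in the scrambled and 31042900 ± 3126580 in the knockdown group (SD, n = 4 each), and 18274 to 20494 genes had at least 1 read in a library. The design asks how loss of the circular RNA alters cortical mRNA levels.

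The neurexin genes Nrxn3 and Nrxn2, which encode presynaptic adhesion proteins, were read first. Nrxn3, the host gene of the circle (ENSRNOG00000047574, chromosome 6, 113898420 to 114067055, rn6), had 344, 114, 216 and 261 counts in scrambled replicates 1, 3, 4 and 5 and 430, 381, 82 and 268 in knockdown replicates 1 to 4. Its log2 fold change was 0.20 with a standard error of 0.48 (adjusted p = 0.948, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Nrxn2 (ENSRNOG00000021103, chromosome 1, 221801524 to 221908045) was at 939 ± 36.9 CPM in scrambled and 797 ± 69.5 CPM in knockdown libraries (SD, n = 4 each). All 4 knockdown values of Nrxn2 lay below all 4 scrambled values, and its log2 fold change of −0.24 did not pass (edgeR adjusted p = 0.833). Poly-T selected libraries count mainly linear mRNA, so these values do not check the level of the circle. The gene model of Nrxn3 spans 1293 bp of exons, against 7152 bp for that of Nrxn2. Whether the Nrxn3 model covers all exons of the gene was not checked, so its counts may miss part of the host mRNA. The Nrxn3 fold change turned to −0.06 without scrambled replicate 3, to −0.01 without knockdown replicate 2 and to −0.26 with 1 surrogate variable. It was 0.51 without scrambled replicate 1, 0.48 without knockdown replicate 3, 0.11 without scrambled replicate 4 and 0.04 without knockdown replicate 1.

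No gene passed the threshold between the groups. The edgeR test called 0 of 16573 genes, 0 higher and 0 lower, with a smallest adjusted p of 0.833. At an unadjusted p under 0.05 there were 926 genes, 395 higher and 531 lower in the knockdown libraries, where 829 are expected by chance. The values of the groups did not overlap in 576 genes, 3.48% of those tested, against 2.86% expected by chance. The biological coefficient of variation was 0.265. Of the other count tools run, limma-voom called 0 genes and DESeq2 called 6, namely Dlgap3, Map3k10, C1qtnf4 and H1fx at lower and Tagln3 and Oxr1 at higher levels. Tagln3 was called by edgeR when knockdown replicate 3 was left out, and a gene model without a symbol was called when knockdown replicate 2 was left out.

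Among the 10 genes with the smallest p at higher levels in knockdown libraries, Tagln3 had by far the largest difference. Tagln3 (ENSRNOG00000059539, chromosome 11, 60072727 to 60086553) encodes a neuronal actin-binding protein of the transgelin family. It was at 17.8 ± 2.94 CPM in scrambled and 107 ± 63.4 CPM in knockdown libraries (SD, n = 4 each), a log2 fold change of 2.58 with a standard error of 0.51. Another gene model also carries the symbol Tagln3, and its level is not given here. Knockdown replicate 3 was at 28.8 CPM and the other 3 knockdown libraries at 105 to 184 CPM. The other 9 genes had log2 fold changes of 0.25 to 0.55. They include Esrrg, an orphan nuclear receptor (0.47, standard error 0.10), and Oxr1, which protects against oxidative damage (0.32, standard error 0.07). Scn4b, a sodium channel beta subunit (0.55, standard error 0.13), and Kcnab1, a potassium channel beta subunit (0.38, standard error 0.09), are both ion channel subunits. Cbln2, a secreted ligand of neurexins, went from 74.7 ± 7.05 to 95.3 ± 5.25 CPM (SD, n = 4 each), a log2 fold change of 0.35 with a standard error of 0.08. Arntl, which encodes the clock transcription factor BMAL1, had a log2 fold change of 0.35. The remaining genes were Slc3a1 (0.38), an amino acid transporter subunit that lies within 1 kb of Prepl, Etl4 (0.25) and the chaperonin subunit Cct2 (0.41). Knockdown and scrambled values overlapped for Cct2 alone, but picking genes by smallest p favours genes without overlap. Each of the 10 genes had an adjusted p of 0.833 in the edgeR test.

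The 10 genes with the smallest p at lower levels were led by Lcat (ENSRNOG00000019573, chromosome 19, 37913336 to 37916813), the enzyme that esterifies cholesterol on lipoproteins. Lcat was at 21.5 ± 2.38 CPM in scrambled and 10.3 ± 2.53 CPM in knockdown libraries (SD, n = 4 each), a log2 fold change of −1.06 with a standard error of 0.18. Dlgap3 (ENSRNOG00000014302, chromosome 5, 145257714 to 145304536), a scaffold of the postsynaptic density also known as SAPAP3, was at 1035 ± 37.7 and 800.5 ± 48.9 CPM (SD, n = 4 each), a log2 fold change of −0.37 with a standard error of 0.07. Prr7, another postsynaptic protein, had a log2 fold change of −0.38 and lies within 1 kb of Dbn1. Lcat and Map3k10 lie within 1 kb of Slc12a4 and Ttc9b. Map3k10, a mixed-lineage kinase (−0.34), the linker histone H1fx (−0.35), the secreted protein C1qtnf4 (−0.28), Sowaha (−0.33) and Limd2 (−0.33) had standard errors of 0.06 to 0.08. Igfbp7, a secreted binding protein of insulin-like growth factors, had −0.26, and its model overlaps those of Polr2b and Rpl39. Med22, a Mediator subunit, had the largest log2 fold change, −3.09 with a standard error of 0.72, at low counts. It was at 7.12 and 5.74 CPM in scrambled replicates 1 and 5, at 1.31 and 0.745 CPM in scrambled replicates 3 and 4, and at 0.326 to 0.661 CPM in knockdown libraries. Med22 is likewise the symbol of another gene model whose level is not given here. All 10 had an adjusted p of 0.833 in the edgeR test. The scrambled and knockdown values of each did not overlap, which follows largely from picking genes by smallest p.

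**Figure D1:**
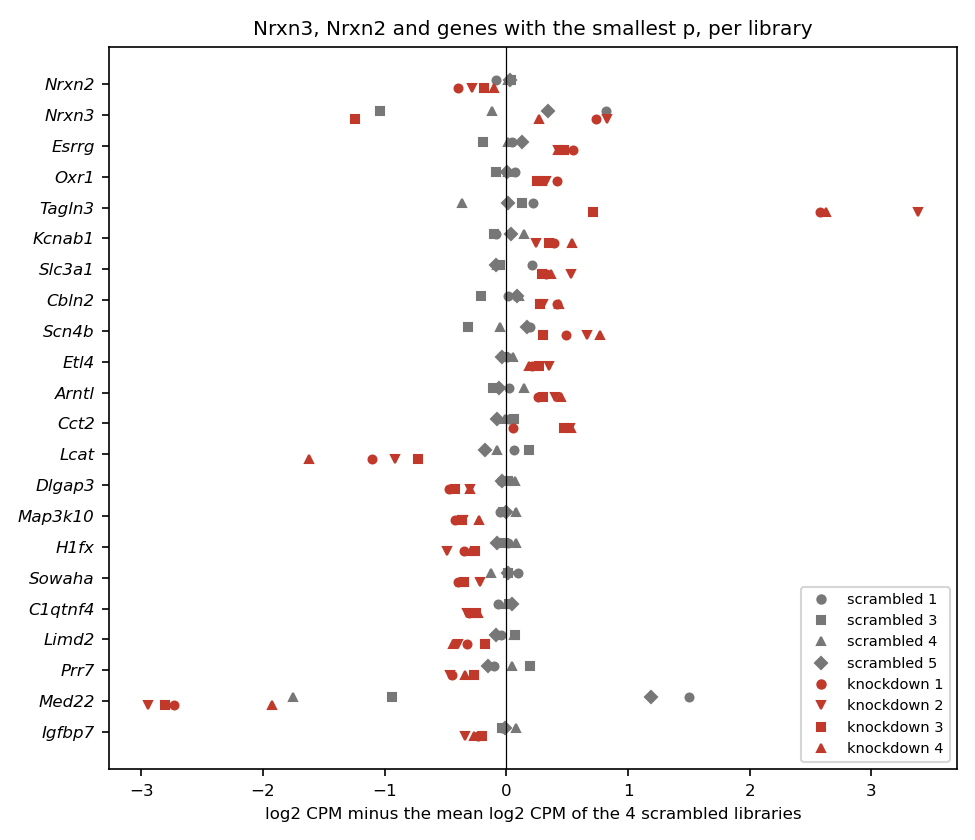
Each point is 1 library, plotted as log2 CPM minus the mean log2 CPM of the 4 scrambled libraries (x axis), for Nrxn3, Nrxn2 and the 20 genes with the smallest p (y axis), with scrambled libraries in grey and knockdown libraries in red. Nrxn3 scatters within both groups, Tagln3 is at 28.8 CPM in knockdown replicate 3, and Med22 is lower in scrambled replicates 3 and 4 than in replicates 1 and 5.

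Of the 42 gene lists, 6 passed the camera test at its preset correlation, 5 lower and 1 higher in the knockdown libraries. With an estimated correlation 0 lists passed (smallest adjusted p = 0.967 with an estimated correlation) and 0 passed fry (smallest adjusted p = 0.963). The count was 10 lists without scrambled replicate 3 and 10 without knockdown replicate 4. No list score differed between the groups in an exact permutation test (smallest p = 0.0857, for the red blood cell list). The lower lists were those of transcripts for protein synthesis, respiration, blood and phagocytes, and the higher list that of myelin genes.

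Cytosolic ribosomal protein genes had a median log2 fold change of −0.18, with 78 of 84 members below 0 (camera adjusted p = 4.2e-15, and adjusted p = 0.967 with an estimated correlation). Rpl29 had a log2 fold change of −0.31 and Rps2 −0.25. Nuclear genes for oxidative phosphorylation subunits had a median of −0.10, with 66 of 75 below 0 (camera adjusted p = 2.5e-06, and adjusted p = 0.967 with an estimated correlation). Atp5g2, an ATP synthase subunit, had −0.21 and Cox8a, a cytochrome c oxidase subunit, −0.20. Without scrambled replicate 4 or knockdown replicate 2 the median of this list was −0.06. Transcripts of the mitochondrial genome had a median of −0.16, with 10 of 12 below 0 (camera adjusted p = 0.00144, and adjusted p = 0.967 with an estimated correlation). Mt-cox3 had −0.28 and Mt-co2 −0.23, whereas Mt-nd4 had 0.63. The mitochondrial call was lost without scrambled replicate 5 (adjusted p = 0.101) and without knockdown replicate 2 (adjusted p = 0.123). It was also lost in all 4 fits of the FPKM values (adjusted p = 0.0596 to 0.542). Ribosomal protein genes can share reads with processed pseudogenes and near-identical copies, which was not measured, so single members are uncertain. The log2 ratio of genes over 4232 bp to genes under 1437 bp, a measure of transcript length in a library, was −0.08 ± 0.15 in scrambled and 0.09 ± 0.16 in knockdown libraries (SD, n = 4 each, exact permutation p = 0.143). With the length trend of each library removed, an alternative chosen after seeing the data, the medians of the ribosomal, respiratory and mitochondrial lists were −0.05, −0.01 and −0.07, and the ribosomal list alone of these kept its call. The respiratory list also lost its call (median −0.04, adjusted p = 0.365) without scrambled replicates 3 and 4 and knockdown replicate 3, left out together after seeing the data.

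All 7 tested red blood cell genes were below 0, with a median log2 fold change of −1.14 (camera adjusted p = 4.8e-08, and adjusted p = 0.967 with an estimated correlation). Alas2, the erythroid enzyme of haem synthesis, had −1.23, the haemoglobin genes Hbb −1.14 and Hba2 −1.12, and Hbb-b1 −0.84. Hbb-b1 passed when adjusted over the list alone (edgeR adjusted p = 0.0162) and not over all genes. Haemoglobin genes are near-identical copies that can share reads. Summed haemoglobin was 1237 ± 751 CPM in scrambled and 584 ± 167 CPM in knockdown libraries (SD, n = 4 each, exact permutation p = 0.0857), with 2314 CPM in scrambled replicate 3. These haemoglobin values are CPM of the library totals, without the TMM factors. Without that library the median was −0.65 and the list kept its camera call. Phagocytic myeloid genes had a median of −0.38, with 18 of 21 below 0 (camera adjusted p = 0.0138, and adjusted p = 0.967 with an estimated correlation). The lysosomal membrane protein gene Cd63 had −0.20 and lysozyme Lyz2 −0.38. This call was lost without scrambled replicate 4 (median −0.02), scrambled replicate 5 (adjusted p = 0.101) or knockdown replicate 2 (adjusted p = 0.173), and the median was −0.62 without scrambled replicate 3. It was also lost with limma-voom (median −0.21, adjusted p = 0.093), in 2 of the 4 fits of the FPKM values (adjusted p = 0.0546 and 0.0596) and with the length trend removed (adjusted p = 0.0728). With a length trend fitted on genes outside the lists removed, 94.3% of the score difference between the groups remained. It was −0.30 before and −0.28 after, with a standard error of 0.46 each.

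Oligodendrocyte and myelin genes had a median log2 fold change of 0.15, with 22 of 22 members above 0 (camera adjusted p = 0.00292, and adjusted p = 0.967 with an estimated correlation). Ermn, a cytoskeletal protein of myelin, had 0.55, the receptor Gpr37 0.32 and Mal, a myelin proteolipid, 0.26. With the libraries taken as unpaired, scores within each group spread more widely than the groups differed, at −0.10 ± 0.44 in scrambled and 0.10 ± 0.26 in knockdown libraries (SD, n = 4 each, exact permutation p = 0.429). Replicate numbers 1, 3 and 4 occur in both groups, and whether they pair animals is open. The score was −0.52 in scrambled and 0.02 in knockdown libraries for number 1. It was −0.40 and 0.33 for number 3, and 0.07 and 0.29 for number 4. The knockdown score was thus the higher for each shared number. The call was lost without scrambled replicate 1 (median 0.03) and without knockdown replicate 3 (median 0.07), and the median was 0.05 without scrambled replicate 3, 0.36 without scrambled replicate 5 and 0.25 without knockdown replicate 2. Leaving out scrambled replicates 3 and 4 and knockdown replicate 3 together, the libraries lowest in long transcripts and chosen after seeing the data, gave a median of −0.0027.

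**Figure D2:**
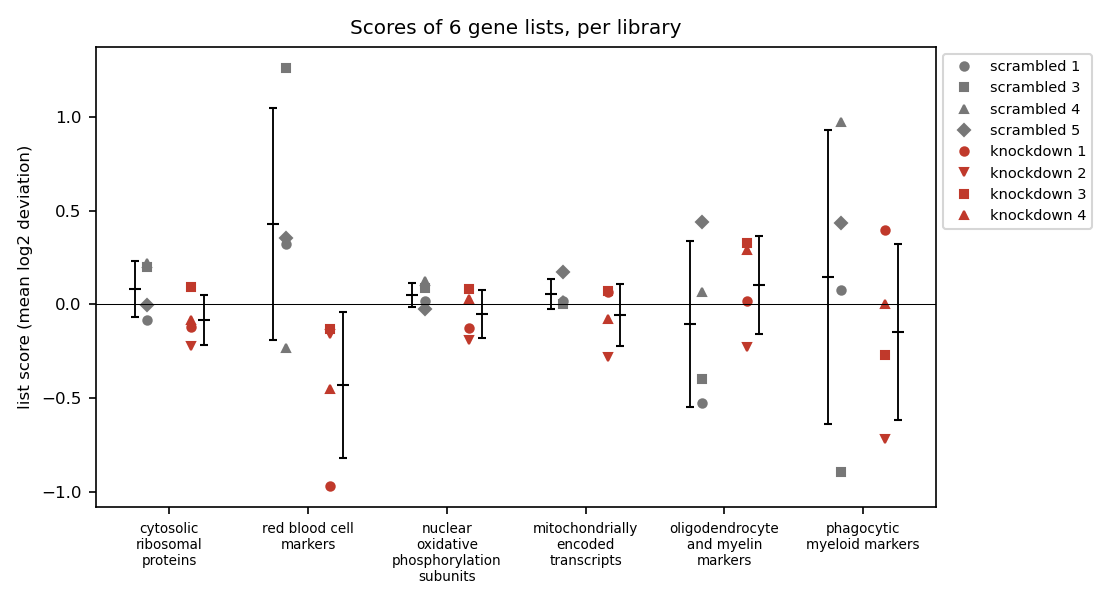
Each point is the score of a gene list in 1 library (y axis, mean log2 deviation of the members from their mean over 8 libraries), for the 6 lists past the preset camera threshold (x axis), with scrambled libraries in grey, knockdown libraries in red and bars at mean ± SD of 4 libraries. The ranges of the groups overlap in every list, and scrambled replicate 3 is highest in the red blood cell list at 1.26.

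The other 36 lists did not pass, with adjusted p from 0.0566 to 0.983 and medians from −0.39 to 0.15. Neurexins and their synaptic partners had a median log2 fold change of 0.05, with 17 of 27 members above 0 (adjusted p = 0.416). Clstn2, a calsyntenin, had 0.54 and Lrrtm2, a postsynaptic ligand of neurexins, 0.36, and Cbln2 alone passed when adjusted over the list alone (edgeR adjusted p = 0.0447). The postsynaptic density list had the smallest adjusted p of these lists (0.0566). Its camera direction was lower and its mean −0.04, whereas its median was 0.01 with 12 of 23 members above 0. Dlgap3 passed when adjusted over the list alone (edgeR adjusted p = 0.00893), Dlg4, the scaffold PSD-95, had a log2 fold change of −0.26 and Ppp1r9b, which encodes spinophilin, −0.40. This list passed with upper-quartile scaling, without a filter on low counts, with DESeq2, with 1 surrogate variable, at an adjusted p threshold of 0.10, and when scrambled replicate 3 or 4 or knockdown replicate 2 or 4 was left out. Presynaptic release genes had a median of 0.03 (adjusted p = 0.505), glutamate receptors 0.002 (adjusted p = 0.915), and GABA receptors and synthesis 0.11 (adjusted p = 0.372). The RNA-binding regulators of splicing and circular RNA had a median of 0.10 with 22 of 31 above 0 (adjusted p = 0.156). In that list Elavl4 had 0.25 and Nova2, a neuronal splicing factor, −0.34. The RNA interference machinery had a median of 0.04 (adjusted p = 0.505), the interferon response 0.15 (adjusted p = 0.488) and activity-regulated immediate early genes −0.10 (adjusted p = 0.547). The interferon list passed without scrambled replicate 4, knockdown replicate 1 or knockdown replicate 4, and the immediate early and cholesterol synthesis lists without knockdown replicate 4. By mean interferon score, knockdown libraries lay above scrambled ones without scrambled replicate 4 or knockdown replicate 4. They lay below them without knockdown replicate 1, so these passes do not add up to a higher interferon response. The GABA and voltage-gated channel lists passed without knockdown replicate 3.

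Markers of cell types other than oligodendrocytes, phagocytes and red cells did not pass in the edgeR fit of the 8 libraries. Astrocyte markers had a median log2 fold change of −0.08 (adjusted p = 0.0752) and reactive astrocyte markers −0.15 with 15 of 20 below 0 (adjusted p = 0.121), where Cd44 had −1.07 and Gfap, the astrocyte intermediate filament, −0.43. Microglia markers were at −0.03 and endothelial markers at −0.00046 (adjusted p = 0.915 and 0.983). Interneuron markers had a median of 0.003, deep-layer excitatory neuron markers 0.05 and upper-layer markers 0.03 (adjusted p = 0.505, 0.505 and 0.915). Astrocyte, reactive astrocyte and infiltrating leukocyte markers passed without a filter on low counts and with DESeq2, and the astrocyte and leukocyte markers also with FPKM values without a filter. Astrocyte markers passed with 1 surrogate variable, at an adjusted p threshold of 0.10, and without scrambled replicate 3 or 4 or knockdown replicate 2. Reactive astrocyte markers passed without scrambled replicate 3 or knockdown replicate 1 or 3, microglia markers without knockdown replicate 1, and deep-layer markers without scrambled replicate 3 and with 1 surrogate variable. When scrambled replicates 3 and 4 and knockdown replicate 3 were left out together, a choice made after seeing the data, the postsynaptic density, microglia, astrocyte, reactive astrocyte, fibroblast and meningeal, and deep-layer lists passed. Median, mean and test direction also differed in sign for the interneuron, glutamate receptor, monoamine receptor, unfolded protein, p53, olfactory bulb, cholesterol synthesis, oligodendrocyte precursor, endothelial and choroid plexus lists, none of which passed with all 8 libraries. Across all 42 lists, 8 members passed when adjusted over their list alone and 0 when adjusted over all genes. Besides those named above these were Scn4b in the striatal list, C1ql1 among oligodendrocyte precursor markers (−0.35), the opioid peptide precursor Penk (−0.34), Arntl in the clock list and the adrenergic receptor Adra2c (−0.37).

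The libraries differed among themselves along axes on which the siRNA groups were interspersed. The first principal component held 35.1% of the variance, with scrambled replicate 3 at 70.0, knockdown replicate 3 at 32.1 and scrambled replicate 4 at 18.2, and the other 5 libraries below 0 (exact permutation p = 0.543 between the groups). The second held 19.1% and ran from −42.0 in scrambled replicate 3 to 45.4 in scrambled replicate 4 (exact permutation p = 0.914). Reads of mitochondrial genes made up 10.2% to 13.8% of a library. They were 12.6 ± 0.82% in scrambled and 11.4 ± 1.02% in knockdown libraries (SD, n = 4 each, exact permutation p = 0.2).

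**Figure D3:**
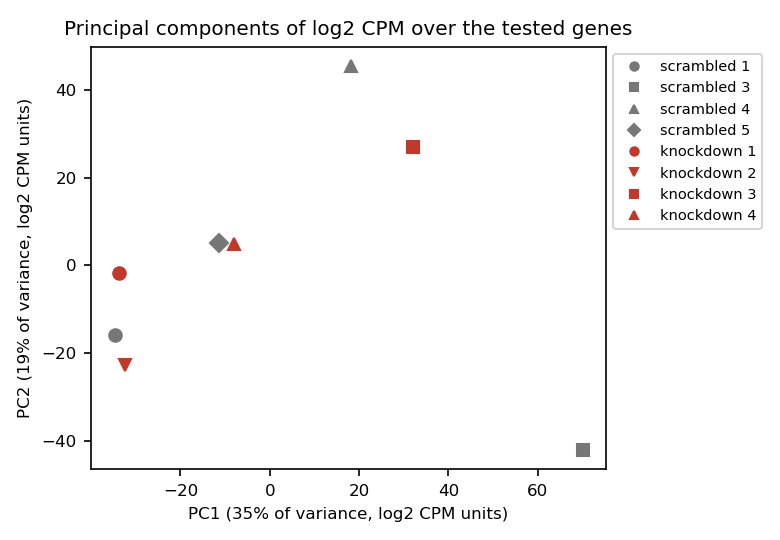
Each point is 1 library, placed by its first (x axis, 35.1% of variance) and second (y axis, 19.1% of variance) principal component of log2 CPM over the tested genes, with scrambled libraries in grey and knockdown libraries in red. Scrambled replicate 3 lies apart at 70.0 on the first component, and the groups are interspersed.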

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

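The tests of gene length, blood content, library composition and neighbouring genes, and the counts of splits other than that for genes past the edgeR threshold, were chosen after the results were seen. A library was singled out where its gap to the nearest of its own group took up most of the group's range. Of 152 groups of 4 values examined, 11 exceeded the 95% critical value of Dixon's ratio, where chance alone gives about 1 in 20.

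Scrambled replicate 5 stood apart in its share of mitochondrial reads, 13.8% against 12.1% to 12.3% in the other scrambled libraries, and in the score of mitochondrially encoded transcripts, 0.17 against 0.00 to 0.03. It also had the highest score of oligodendrocyte precursor markers in its group, 0.28 against −0.11 to −0.06. Knockdown replicate 1 had 1.24% of reads on ribosomal RNA genes against 1.07% to 1.09% in the other knockdown libraries, and Cct2 at 88.0 CPM against 117 to 122 CPM. Both values lay within the range of the scrambled libraries, 1.12% to 1.24% and 80.1 to 88.6 CPM. Scrambled replicate 1 had Slc3a1 at 95 CPM against 77.7 to 79.5 CPM and a fibroblast and meningeal marker score of 0.40 against −0.13 to −0.07. Scrambled replicate 4 had Igfbp7 at 201 CPM against 185 to 188 CPM and a glutamate receptor score of −0.13 against 0.03 in the other 3. Knockdown replicate 4 had Med22 at 0.662 CPM against 0.326 to 0.378 CPM. Knockdown replicate 3 had a voltage-gated channel score of −0.43 against 0.16 to 0.19 in the other knockdown libraries.

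Chance cannot be excluded for the differences between the siRNA groups. At an unadjusted p under 0.05, 8 of 35 splits of the 8 samples gave at least the real 926 genes (highest other 4184), and 18 of 35 gave at least the 6 genes DESeq2 called (highest other 2155). The 6 gene lists past the preset camera threshold were matched or exceeded by 33 of 35 splits, with a highest other count of 17. For genes past the edgeR threshold the splits decide nothing, since the real count was 0 and all 35 splits must give at least that, but the highest other split gave 697. That split set scrambled replicate 1 and knockdown replicates 1, 2 and 4 against the rest. It differs from the siRNA groups only in that scrambled replicate 1 and knockdown replicate 3 change sides, so it lies largely along them. The log2 ratio of long to short genes was 0.01 to 0.26 in the libraries of its first side and −0.22 to −0.03 in the rest. Whether transcript length gives this structure was not tested.

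The lower ribosomal and respiratory lists may reflect differences in transcript length between libraries. The median gene model was 599 bp in the ribosomal and 711 bp in the nuclear respiratory list, against 2215 bp over all tested genes, and across tested genes, which are not independent replicates, log2 fold change and length had a Spearman correlation of 0.20, or 0.36 over the 9561 genes with a mean log2 CPM over 3. When a length trend fitted on genes outside the lists was removed, 9.40% of the respiratory list's difference between groups remained (−0.10 before, standard error 0.07, and −0.01 after, standard error 0.03), so length bias could account for it. The respiratory median of −0.10 lay at percentile 97 of 10000 random lists matched on length and expression. It was thus less low than most of them, whose median was −0.13. Of the ribosomal difference 32.5% remained (−0.17 before, standard error 0.10, and −0.05 after, standard error 0.04), while its median lay below all 10000 matched lists. The random lists were drawn gene by gene, without the co-variation of ribosomal genes (estimated correlation 0.50) or of respiratory genes (estimated correlation 0.51). These ranks therefore can neither show nor exclude a component beyond length. Length and a further component shared by ribosomal genes cannot be told apart. An effect of the siRNA stays open and is untested beyond the group comparison.

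Less blood left in the tissue may give lower red blood cell transcripts, but the relation given here cannot tell it from another shared cause. Alas2, a gene of red cell precursors, followed summed haemoglobin over the 8 libraries, both as CPM with TMM factors. Pearson r was 0.96 (exact permutation p = 0.000322) and Spearman rho 0.90 (exact permutation p = 0.00456). Without the 2 libraries farthest from the median haemoglobin level r was 0.84. Alas2 and the haemoglobin genes belong to the same list and were all lower in the knockdown group. Any cause they share would give such a relation over the pooled libraries. Relations within each group are not given here. Whether scrambled replicate 3 alone carries the difference cannot be told apart, since 57.0% of the list's median remained without it and the score difference of −0.58 then had a standard error of 0.27. Bpgm, at 114 to 137 CPM in all libraries, is a list member with much expression outside blood, and none of the 7 members is in another list. An effect of the siRNA on blood content stays open as well.

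Tagln3, Med22 and Chchd10 showed differences of several fold that were uneven within a group, Chchd10 being chosen after its values were seen. Chchd10, a mitochondrial protein gene (chromosome 20, 13665031 to 13667333), was at 172 to 339 CPM in scrambled libraries, at 17.7 to 27.4 CPM in knockdown replicates 1, 2 and 3 and at 145 CPM in knockdown replicate 4 (log2 fold change −2.03, standard error 0.72, edgeR adjusted p = 0.833). At least 81.2% of each log2 fold change remained with 1 surrogate variable. This variable was estimated with the siRNA groups in its model. It therefore cannot decide whether a shift along the main axis of library composition adds to the group differences. The unevenness within groups was not tested against this axis. Med22 was low in scrambled replicates 3 and 4, where the surrogate variable was 0.47 and 0.36, against −0.40 and −0.04 in replicates 1 and 5. Tagln3 was at 28.8 CPM in knockdown replicate 3, where it was 0.43. For Chchd10 in knockdown replicate 4 it was −0.03. Reads counted for a neighbouring gene instead are argued against for Tagln3 and Chchd10. The sum over each gene and its neighbours within 30 kb showed at least 99.95% of the gene's own difference. Reads left uncounted would not show in this sum. The Chchd10 neighbours together held a mean of 0.018 CPM in scrambled and 0.10 CPM in knockdown libraries. For Med22 such a passage of reads cannot be told apart, since the sum showed 178% and the neighbours differed by −2.57 CPM with a standard error of 11.5 CPM. A sequence variant carried by some of these outbred animals, or reads shared with the second gene model that carries the symbol of Tagln3 and of Med22, may give such levels and was not tested, and an effect of the siRNA stays open.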

How the results depend on the processing

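The alternatives with the length trend removed and without 3 libraries were chosen after seeing the data, the others beforehand. Across 26 alternatives the count of changed genes was 0 except for 6 with DESeq2 (2 higher and 4 lower), 3 without the 3 libraries lowest in long transcripts (3 lower), and 0 to 1 when single libraries were left out (0 to 1 higher, 1 without knockdown replicate 2 or 3). The cause of these was not tested. The Nrxn3 log2 fold change was −0.26 with 1 surrogate variable and ranged from −0.056 without scrambled replicate 3 to 0.51 when single libraries were left out. Each of these moves was smaller than the standard error in the report, and their cause was not tested.

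The number of lists past the threshold was 10 without a filter on low counts, 10 with DESeq2, 3 with the length trend removed, 10 without the 3 libraries, 0 with an estimated correlation, 0 with fry, and 4 to 10 when single libraries were left out (10 without scrambled replicate 3 or knockdown replicate 4). The cause of these shifts was not tested. The myelin list had a median of −0.0027 without the 3 libraries. Of the other values, 559 of named genes and 135 of described lists kept direction and side of the threshold, 8 of named genes newly passed and 32 of lists no longer passed. Med22 was not tested with a CPM of at least 1 in 4 samples.

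Replicate numbers 1, 3 and 4 occur in both groups, and with the number as a block over these 6 libraries 0 genes passed (0 higher, 0 lower), 7 lists passed and the Nrxn3 log2 fold change was 0.04. At an unadjusted p under 0.05 it gave 1692 of 16721 genes, against 926 of 16573 in the unblocked fit of all libraries. An unblocked fit without scrambled replicate 1 gave 1697 of 16846. In the block fit the mitochondrial and phagocytic lists lost their call (adjusted p = 0.455 and 0.491, camera at its preset correlation). The myelin median was 0.49 (adjusted p = 9.6e-37, camera at its preset correlation), against 0.15 in the unblocked fit of all libraries. The estimated correlation of the myelin list was 0.81. The block fit also left out scrambled replicate 5, with the highest myelin score (0.44), and knockdown replicate 2, with the lowest knockdown score (−0.23). No unblocked fit of these 6 libraries was made, so these changes cannot be put down to the block. Deviations from the group mean had Pearson correlations of 0.37, 0.30 and 0.087 and Spearman correlations of 0.42, 0.35 and 0.12 over genes for the numbers 1, 3 and 4. Knockdown replicates 1, 3 and 4 and scrambled replicates 1 and 3 correlated best with their own number, and scrambled replicate 4 with knockdown replicate 3 (Pearson 0.22). The labels give no shared animal or batch and 1 Pearson value is under 0.1, so the numbers were not taken to pair animals. Which correlation to use was not fixed beforehand, and the Spearman values, all over 0.1, leave pairing open.

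Seed matches of the siRNA, fixed as a result with 4 alternatives, were not run because no transcript sequences were used. Nrxn3 had 82 to 430 counts per library, and no comparison of depth with the spread between animals was made.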

Other observations

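The tests in this part were chosen after the values were seen. Interferon-responsive genes had the widest spread between animals of all 42 lists, and this spread crossed the siRNA groups. The score was 1.14 in scrambled replicate 4 and 1.248 in knockdown replicate 1, against −1.54 in scrambled replicate 3 and −0.83 in knockdown replicate 4. Mx1, an antiviral GTPase, was at 41.9 CPM in scrambled replicate 4 and 41.3 CPM in knockdown replicate 1, and at 1.28 CPM in scrambled replicate 3. Cxcl10, an interferon-induced chemokine, was at 20.8 and 9.92 CPM in the first pair and at 0.209 CPM in scrambled replicate 3. Ifit1 did not follow this order, with 17.6 CPM in scrambled replicate 4, 8.67 CPM in knockdown replicate 3 and 0 CPM in knockdown replicate 1. The inflammatory cytokine and NF-kappaB list was likewise highest in scrambled replicate 4 (0.73) and lowest in scrambled replicate 3 (−0.96).

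Myelin genes also varied between animals within both siRNA groups. Mbp, a major myelin protein gene, ran from 1070 CPM in scrambled replicate 1 to 2817 CPM in scrambled replicate 5, and Mag from 72.2 to 193 CPM in the same libraries. Mbp was at 1403 to 2481 CPM in the knockdown libraries. Neuronal markers were abundant in all libraries, with Snap25 at a mean of 2579 CPM and the cortical glutamate transporter gene Slc17a7 at 2153 CPM. The choroid plexus gene Ttr had 0 to 3 counts in a library, and Cldn5, an endothelial tight junction gene, is listed at 0 counts in all libraries although the endothelial list as a whole had 18 tested members.

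Levels of Nrxn3, counted on a gene model of 1293 bp, followed the log2 ratio of long to short genes across the 8 libraries. Pearson r was 0.77 (exact permutation p = 0.0271, adjusted 0.0325 over 6 relations, of which 5 are given). Spearman rho was 0.86 (exact permutation p = 0.0107, adjusted 0.0321), and r was 0.86 without the 2 libraries farthest from the median ratio. Nrxn2 went the other way, with r = −0.79 (exact permutation p = 0.0222, adjusted 0.0325) and rho = −0.71 (exact permutation p = 0.0576, adjusted 0.0691), and r = −0.71 without those 2 libraries. The score of neurexins and their partners had r = 0.86 (exact permutation p = 0.00898, adjusted 0.0269) and rho = 0.81 (exact permutation p = 0.0218, adjusted 0.0327), and r = 0.78 without them. The ribosomal score had r = −0.97 (exact permutation p = 0.000124, adjusted 0.000744) and rho = −1 (exact permutation p = 4.96e-05, the smallest 8 libraries can give, adjusted 0.000298), and r = −0.94 without them; ribosomal genes are themselves short, so part of this relation is built in. The myelin score had r = −0.21 (exact permutation p = 0.612) and rho = −0.29 (exact permutation p = 0.501). The list of neurexins and their partners holds Nrxn3 and Nrxn2, so its relation is not separate from theirs. It also holds models over the 4232 bp limit for long genes, such as Nrxn2 (7152 bp) and Lrrtm2 (4715 bp). Part of its relation may thus be built in too.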
